A study of Methanocaldococcus jannaschii with 13 samples.

How the data were processed

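Methanocaldococcus jannaschii, a hyperthermophilic archaeon that makes methane from hydrogen and carbon dioxide, was grown in a high-pressure vessel under 2 pressures (7.8 and 500 atm, the higher one reached with helium) and in 2 volumes of medium (200 and 600 ml) with the same kind of hydrogen and carbon dioxide headspace. The study's title speaks of gas-substrate limitation, and its sample titles mark the 600 ml cultures as mass transfer limited in abbreviated form. RNA was taken in exponential phase, per the series' design text. Each array compared 2 cultures directly, 1 labelled with Cy3 and 1 with Cy5, and no common reference was used. The 13 arrays form 4 comparisons that close a loop over the 4 conditions. These are 500 against 7.8 atm in 200 ml (4 arrays), the same pressures in 600 ml (3 arrays), 600 against 200 ml at 500 atm (3 arrays) and 600 against 200 ml at 7.8 atm (3 arrays). The design text describes the pairs as biological replicates with dye swaps and gives 7 atm where the sample labels give 7.8 atm. One characteristic of replicate 2 of the pressure comparison in 200 ml gives 600 ml for a culture that its other labels place in 200 ml, and that array was used as a 200 ml array and left out in an alternative.

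The deposited values are log2 ratios of the 2 channels of each spot, as read from the values themselves. On 12 of the 13 arrays, 2 raised to the value gave a ratio of small whole numbers (denominator up to 400, relative tolerance 6e-09) for 8.73 to 39.4% of 1500 sampled spots. Powers of e and of 10 gave at most 0.33% and 1.27%, and the remaining array, replicate 1 of the pressure comparison in 200 ml, had been rounded too far for this test (0.33%). The scanner, the handling of background and any normalization by the authors are not given in the sources used here. The ratios were not centred, since the array medians ran from -0.51 to 1.03 on the log2 scale over all spots. They were not turned for dye swaps either, since arrays of opposite dye orientation correlated below 0 across genes within every comparison. For pressure in 600 ml this says little, since those values were -0.08 and -0.19 and the arrays of the same orientation correlated at -0.20. In 200 ml the values with replicate 4 were only -0.10 and -0.05. Whether a deposited value is Cy5 over Cy3 or Cy3 over Cy5 is not stated in the labels, and the values do not settle it. No direction of change is therefore given, and differences are described by size and by side. In the volume comparisons a positive log2 value means the side on which the archaellum genes lie, and in the pressure comparisons the side on which MJ0334 lies. If the ratios are Cy5 over Cy3, the archaellum side is 200 ml and the MJ0334 side is 500 atm. If they are Cy3 over Cy5, the archaellum side is 600 ml and the MJ0334 side is 7.8 atm.

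The table held 7040 spots with no missing value. The platform annotation named a gene for 5703 spots, which stood for 1694 genes, and 1337 spots (19.0%) had no gene and stayed out of the tests. All 5703 named spots matched the gene table of the assembly ASM9166v1, which was used for names and for the order of neighbouring genes only. It gave symbols for 415 genes, and 1279 are called by locus tag. Most genes (1528) had 3 spots, and 166 had 6, 9 or 12. Those 166 genes were printed as several sets of spots that agreed poorly (median r between sets across arrays 0.20, median root mean square difference 0.69 on the log2 scale). They were kept, are named as such where they appear, and were left out in an alternative.

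Each array was centred on the median of its genes, under a rule fixed before the data were examined (any median more than 0.1 from 0), and the spots of a gene were averaged. One joint fit of all 13 arrays was made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with a coefficient for each comparison and a gene-wise dye coefficient. Each comparison was tested against 0, 2-sided, with Benjamini-Hochberg adjustment over 1694 genes, and a gene with an adjusted p under 0.05 is called. The interaction of pressure and volume came from a closed-loop fit of the 4 conditions with a dye coefficient. Standard errors (SE) are the moderated ones of limma with 8 residual degrees of freedom (9 in the closed-loop fit) before moderation, and their medians over genes were 0.16 to 0.19. The number of arrays limits the precision. On simulated ratios drawn with the fitted spread, with 100 genes changed 2-fold and 100 changed 4-fold in each of 10 simulations, the fit called 87% of the 2-fold and 98.6% of the 4-fold changes for the pressure comparison in 200 ml. For the pressure comparison in 600 ml the shares were 80.7 and 97.1%, for volume at 500 atm 80.9 and 98.5%, and for volume at 7.8 atm 82.6 and 96.5%. Between 4.4 and 6.1% of the calls were unchanged genes. The simulated arrays were independent, with no drift with brightness and no deviations shared between arrays, both of which the real arrays had. More genes were changed in each simulation than were called in the real pressure comparisons, which eases the adjusted threshold. The shares hold for that setting only and may be too favourable for the real comparisons.

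Gene lists were fixed before the data were examined, except for the symbol patterns of lists that had been defined by product names. The fixed rule was to use only the listed locus tags if the annotation held no product names. It held none, and the symbol patterns were then written in departure from that rule, before any gene's value was read. Lists defined by product names alone, such as ribosomal proteins and aminoacyl-tRNA synthetases, rest on these patterns. The 24 lists with at least 4 measured members are the methanogenesis pathway, the methyl-coenzyme M reductase I and methyltransferase cluster, hydrogenases and heterodisulfide reductase, formate dehydrogenase, archaellum, A-type ATP synthase, ribosomal proteins, RNA polymerase and general transcription factors, aminoacyl-tRNA synthetases, translation factors, chaperones and proteasome, oxygen and oxidative stress proteins, nitrogen assimilation, acetyl-CoA and pyruvate synthesis, amino acid biosynthesis, methanogenic cofactor synthesis, cobalamin and tetrapyrrole synthesis, purine and pyrimidine synthesis, DNA replication with repair and histones, CRISPR-associated proteins, metal transport, phosphate transport, cell division and the genes of the extrachromosomal elements. Isoprenoid lipid synthesis, the methyl-coenzyme M reductase II cluster and protein export had 2 or 3 measured members and are described by counts. Lists that need product names (restriction-modification, ABC transporters, uncharacterized proteins) were not formed. The others hold only genes with a locus tag fixed in advance or a fitting symbol, and 415 of 1694 genes had a symbol. Lists that rest on symbols, such as ribosomal proteins (16 genes, 15 of them measured), may therefore hold only a part of their class. Lists were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 120 pairs of list and result, beside camera with an estimated correlation and fry.

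Genes named in the text are those called with the same sign on every array of their comparison, up to the 10 largest on each side, a panel of 12 genes, and up to 4 called members of each list, all by a rule fixed before the data were examined. The panel fixed by that rule also held fdhA (MJ1353), which was left out. Panel genes are given singly for volume and mainly as a range for pressure. Genes named outside this rule are said to be so, except where they mark the ends of a run of neighbouring genes. Alternatives fixed before the data were examined were no dye coefficient, the deposited values without centring, scaling of the arrays to one median absolute deviation, the median of the spots, leaving out the noisiest 25% of genes, the replicate number as a block, array weights, a trended and robust variance, fits of the arrays of one comparison only, the closed-loop fit, a 2-fold minimum, the array with the conflicting label left out, and each array left out in turn. Alternatives chosen after the data were seen were a loess of each array's ratios on brightness (span 0.4), and fits without the genes of several spot sets, without the dimmest 25% of genes, and without 2 poorly agreeing arrays. Brightness was recovered from the whole-number ratios behind the log2 values of 12 arrays and is a lower limit for spots whose channels share a common factor. For the remaining array, replicate 1 of the pressure comparison in 200 ml, the loess used the brightness of replicate 2. Figures and list handling used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.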

Results

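Transcript ratios of 1694 genes were read from 13 two-colour cDNA arrays of Methanocaldococcus jannaschii. Each array set 2 cultures side by side that differed either in pressure (500 against 7.8 atm) or in the volume of medium in the vessel (600 against 200 ml), which the study's title ties to limitation by gaseous substrate. Pressure was compared in 200 ml on 4 arrays, 2 in each dye orientation, and in 600 ml on 3 arrays. Volume was compared on 3 arrays at 500 atm and on 3 arrays at 7.8 atm. Every comparison of 3 arrays had 2 arrays in one dye orientation and 1 in the other. The deposited ratios do not say which channel is the numerator, so the values below give the size of each difference and the side on which it lies. Positive log2 values lie on the side of the archaellum genes for volume and on the side of MJ0334 for pressure. All differences are relative to the median gene of each array. Without that centring the median of all genes stood at -0.48 and -0.33 for pressure in 200 and 600 ml, at -0.39 and -0.34 for volume at 500 and 7.8 atm, and at -0.12 for the interaction. The sides of positive values smaller than about these sizes therefore depend on the centring, and negative values keep their side without it.

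Replicate arrays agreed to different degrees. After turning the dye swaps, ratios across genes correlated at 0.40 to 0.82 between the arrays of volume at 500 atm and at 0.31 to 0.78 between those at 7.8 atm. In the pressure comparisons the correlations were 0.05 to 0.88 in 200 ml and -0.20 to 0.19 in 600 ml. Genes are not independent replicates, and these values describe the arrays only. Replicates 1 and 2 of the pressure comparison in 200 ml were the most alike (r = 0.88). They were counted as separate replicates because the design text describes the pairs as biological replicates, and the values do not test that.

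The widest differences between 600 and 200 ml were those of the archaellum genes MJ0891 to MJ0897. At 500 atm, MJ0891, a flagellin of the archaellum filament, differed 42.9-fold between 600 and 200 ml (log2 5.42 ± 0.19 SE, n = 3 arrays, adjusted p = 4.1e-09). MJ0896 differed 36.1-fold, MJ0893 34.7-fold and MJ0895 29.7-fold, all on the same side and on 3 of 3 arrays. After a loess on brightness these 4 genes, in the same order, differed 12.7-, 14.1-, 14.3- and 10.5-fold. Enzymes of the methane pathway lay on that side too, among them hmd, the hydrogen-dependent methylenetetrahydromethanopterin dehydrogenase (7.88-fold), and fhcD, the formyltransferase of the pathway (5.75-fold). After the loess hmd differed 2.64-fold, and fhcD 1.49-fold and was no longer called (adjusted p = 0.146). The S-layer gene sla, which encodes the cell's surface layer protein, differed 7.23-fold (log2 2.85 ± 0.85), with single arrays from 0.89 to 5.04. After the loess sla differed 2.25-fold, and its call ended without any 1 of 6 arrays (adjusted p up to 0.577, without replicate 2 of this comparison). Glutamine synthetase (glnA) differed 5.1-fold (2.35 ± 0.33, adjusted p = 0.00151), and 3.02-fold after the loess.

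In total 293 of 1694 genes (17.3%) were called at 500 atm, 241 on the archaellum side and 52 on the other, and 281 of them had the same sign on all 3 arrays. At least 2-fold differences were found for 135 of the called genes, all of them on the archaellum side. The split between the sides depended on centring and scaling. It was 118 to 155 without centring, 105 to 2 with arrays scaled to one spread and 155 to 81 after a loess on brightness. The count was 180 with the replicate number as a block. The count fell to 19 without replicate 2 of this comparison and to 44 without replicate 3, was 167 without replicate 3 of the pressure comparison in 600 ml, and was 442 without replicate 1 of this comparison.

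All 12 archaellum genes were called at 500 atm (12 also when adjusted over the list alone), with a median of 3.46. Besides those above, MJ0892, a further flagellin, had a log2 ratio of 3.81 ± 0.21 as the mean of several spot sets that disagreed (r = -0.13, root mean square difference 3.74), MJ0897 of 3.73 ± 0.31 and MJ0894 of 3.19 ± 0.32. The other members, given outside the rule for named genes to complete the list, were MJ0898 (1.91), MJ0899 (2.27), MJ0900 (0.81, several spot sets), flaJ (1.83) and flaK (1.31), the last 2 encoding a membrane protein of the archaellum and the prepilin peptidase that processes flagellins. Camera gave an adjusted p of 3.5e-16 for the list, and adjusted p = 0.349 with an estimated correlation. After the loess on brightness the median was 2.17. The archaellum genes named by rule (7, MJ0891 to MJ0897) stayed past the threshold in all 200 of their values over the 29 alternatives and left-out arrays at this pressure, with log2 sizes of 2.09 to 5.57.

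**Figure D1:**
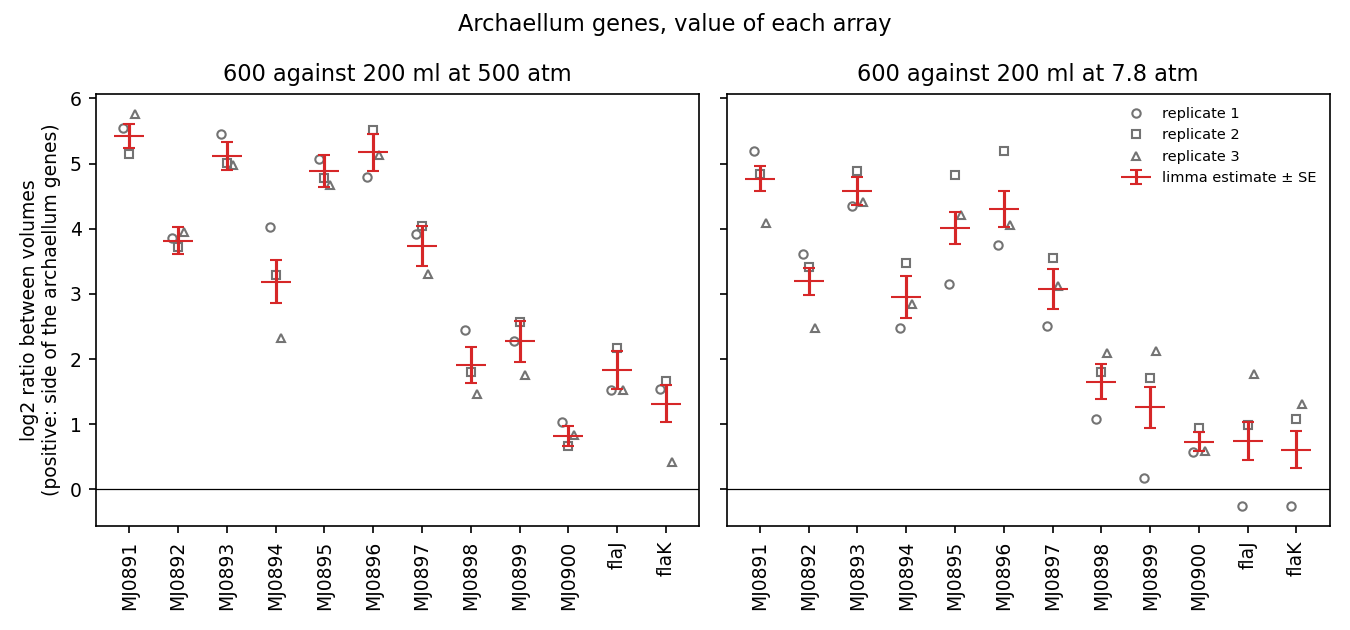
Log2 ratio between 600 and 200 ml for each of the 12 archaellum genes, at 500 atm (left) and 7.8 atm (right), where grey symbols are single arrays, red bars are limma estimates with their SE, and positive values lie on the archaellum side. Genes MJ0891 to MJ0897 lay between 2.32 and 5.77 on every array at 500 atm, and flaJ and flaK were the smallest at 7.8 atm together with MJ0900.

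Of 29 measured methanogenesis genes, 14 were called on the archaellum side at 500 atm and 0 on the other (24 and 1 when adjusted over the list alone). Their median log2 ratio was 1.77 (camera adjusted p = 3e-06, adjusted p = 0.806 with an estimated correlation). After the loess on brightness 4 of them were called and the median was 0.58 (adjusted p = 0.00931). The largest were hmd (2.98 ± 0.62), fhcD (2.52 ± 0.51), mcrG (MJ0845) of methyl-coenzyme M reductase (2.50 ± 0.77) and mer, the methylenetetrahydromethanopterin reductase (2.41 ± 0.73), of which hmd alone was still called after the loess (1.40). In the cluster of methyl-coenzyme M reductase I and the methyltransferase, 5 of 13 genes were called (10 when adjusted over the list alone), including mcrC (2.29), mtrG (2.18) and mtrH (2.16). The median of that cluster was 2.03 (adjusted p = 0.00309, and adjusted p = 0.806 with an estimated correlation), and its call ended without replicate 2 of this comparison (adjusted p = 0.179) and after the loess (0.118, median 0.39, with 1 gene called, mcrC). The catalytic subunit genes mcrA (MJ0846) at 2.31 ± 0.83 (adjusted p = 0.0731) and mcrA (MJ0083) at 1.10 ± 0.38 (0.0664) and MJ1035, the F420-dependent dehydrogenase, at 1.81 ± 0.70 (0.0898) were not called. Neither were the panel genes rpoB (0.98 ± 0.34, adjusted p = 0.0635), thsB (0.87 ± 0.58, adjusted p = 0.269) and MJ0285 (0.01 ± 0.53, adjusted p = 0.991), which encode an RNA polymerase subunit, a thermosome chaperonin and a small heat shock protein. Without replicate 2 of the comparison thsB stood at -0.40, and after the loess at -1.13 with an adjusted p of 0.0125.

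All 9 genes of the A-type ATP synthase were called (9 also when adjusted over the list alone), led by MJ0216 (1.88 ± 0.42), MJ0220 (1.83 ± 0.34), MJ0217 (1.62) and MJ0219 (1.15), with a median of 1.11 (adjusted p = 6.72e-05, and adjusted p = 0.754 with an estimated correlation). After the loess 3 of the 9 were called, and the median was 0.76 (adjusted p = 0.00185). Among 31 hydrogenase and heterodisulfide reductase genes, 3 were called on the archaellum side, frhA (2.05 ± 0.63), vhuG (2.07 ± 0.51) and hdrC (MJ0864; 1.36 ± 0.39), and the maturation gene hypB lay on the other side (-0.43 ± 0.14). None of the 31 passed when adjusted over the list alone, the list median was 0.01 (adjusted p = 0.735), and after the loess frhA stood at -0.11 and hdrC at -0.04, while vhuG stayed called at 1.81.

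Ribosomal protein and amino acid synthesis genes were the remaining lists that camera called for volume at 500 atm. Of 15 measured ribosomal protein genes with a symbol 6 were called (7 when adjusted over the list alone; median 1.03, adjusted p = 0.000755), among them rpmD (1.98 ± 0.47), rpsJ (1.60), rpsB (1.56, several spot sets) and rpl4p (1.44). The ribosomal list had adjusted p = 0.806 with an estimated correlation, and its call ended without replicate 2 (0.0876). After the loess the ribosomal median was 0.64, with 4 genes called. Of 42 amino acid synthesis genes 11 were called (15 and, on the other side, 1 when adjusted over the list alone; median 0.38, adjusted p = 0.001). They included asd (1.75 ± 0.24), dapA (1.45), ilvC (1.43) and argH (1.30), and the list had adjusted p = 0.754 with an estimated correlation and 0.0708 without centring. Single called genes of lists that camera did not call as a whole included cfbA, the metal chelatase of cobalamin and coenzyme F430 synthesis (1.71 ± 0.18), purD (1.51), guaB (1.29) and purT (1.16) of purine synthesis, and the proteasome genes psmA (1.41) and psmB (1.12). Others were the division genes ftsZ (MJ0622) at 1.83 and ftsZ (MJ0370) at 1.25, minD (MJ0547) at 1.31, and csm3 (2.44), csm4 (2.03) and cas10 (1.76) of a type III CRISPR system. Smaller called ones were MJ0384 (0.68), the aminoacyl-tRNA synthetase genes alaS (0.99), glyS (0.71), serS (0.61) and ileS (0.55), and cooS (1.28) and porD (0.80) of acetyl-CoA and pyruvate synthesis. So were the cofactor genes cofG (0.64), mptA (0.63) and cofH (0.55), cobA (0.55), guaA (0.89), lonB (0.92), prf1 (0.92), MJ0732 (1.17), cbiM (MJ1569; 1.18) and cbiM (MJ1091; 0.57). On the other side the largest with one sign on all arrays were MJ0573 (-0.97 ± 0.29), MJ0998 (-0.93 ± 0.25), MJ1207 (-0.91 ± 0.18) and MJ1544 (-0.86 ± 0.22), and MJ1078, MJ1485, MJ1031, MJ1310, MJ0565 and MJ0023 lay between -0.76 and -0.73. Of the 78 named genes called at 500 atm, 14 were called whichever array was left out, namely MJ0891 to MJ0897, MJ1155.1 (2.56, from spot sets that disagreed at r = -0.64 and a root mean square difference of 3.87), glnA, asd, cfbA, purD, minD and rpsB. The calls of the other 64 ended without at least 1 array, 63 of the 64 without replicate 2 and 60 without replicate 3 of this comparison. After the loess 52 of the 78 were called and 26 were not. The latter were MJ1155.1 (0.98), fhcD (0.57), mcrG (0.92), mer (0.30), mtrG (1.14), mtrH (0.80), frhA, hdrC, hypB, MJ0216 (0.76), MJ0220 (0.66), MJ0219 (0.76), csm3 (1.02), cas10 (0.59) and MJ0384. They also included ftsZ (MJ0370; 0.65), glnK1 (MJ0059; 0.65), rpl4p, serS, ileS, prf1, cooS, dapA, MJ1485, MJ0565 and MJECL26. Besides the archaellum genes, hmd, sla and glnA, some genes that stayed called also fell by more than 1.5 times in fold. They were rpmD (3.95-fold to 2.54-fold), ftsZ (MJ0622; 3.55 to 1.80), asd (3.35 to 2.19), MJ0217 (3.07 to 1.87), purD (2.85 to 1.85) and guaB (2.44 to 1.45). MJ0023 grew, from -0.73 to -1.50 in log2.

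At 7.8 atm the comparison of volumes again had MJ0891 to MJ0897 as its 7 largest called genes. MJ0891 differed 27.3-fold (log2 4.77 ± 0.19, n = 3 arrays, adjusted p = 1.8e-08), MJ0893 23.8-fold, MJ0896 19.8-fold and MJ0895 16.2-fold. After the loess on brightness these 4 genes, in the same order, differed 14.1-, 10.9-, 8.7- and 9.07-fold. MJ0892 was at 3.20 ± 0.21 (several spot sets), MJ0897 at 3.08 ± 0.31 and MJ0894 at 2.96 ± 0.32. Of the 12 genes 10 were called (11 when adjusted over the list alone), with a median of 3.02 (camera adjusted p = 2.72e-18, adjusted p = 0.349 with an estimated correlation). The exceptions were flaJ (0.74 ± 0.29, adjusted p = 0.138) and flaK (0.61 ± 0.28, adjusted p = 0.196). The loess median was 2.14, and the genes MJ0891 to MJ0897 stayed past the threshold in all 200 of their values over the 29 alternatives and left-out arrays, at log2 sizes of 2.10 to 5.02.

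Fewer genes were called at 7.8 atm than at 500 atm, 93 (5.5%), with 83 on the archaellum side and 10 on the other, and all 93 had the same sign on the 3 arrays. At least 2-fold differences were found for 51, all on the archaellum side. Without centring 64 genes were called (56 to 8), of which 28 were among the 93. After the loess on brightness the split was 56 to 18, with 55 of the 93 still called, and the count was 57 with the replicate number as a block. The count moved by more than 1.5 times without replicate 1 (24) or replicate 2 (13) of this comparison. It also did so without replicate 1 (41), 2 (57) or 3 (48) of the pressure comparison in 200 ml, without replicate 3 of that in 600 ml (43), and without replicate 1 (149) or 3 (52) of the volume comparison at 500 atm. The order of the 2 pressures turned in fits of each comparison's own arrays. Without a dye coefficient these called 163 genes at 7.8 atm and 14 at 500 atm, and with one 207 and 137. It also turned without replicate 2 (129 and 19) or 3 (52 and 44) of the volume comparison at 500 atm.

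Outside the archaellum, the genes named by rule at 7.8 atm included csm3 (2.09 ± 0.49), fhcD (1.94 ± 0.51), MJ1155.1 (1.86 ± 0.20, several spot sets), fwdA (1.72 ± 0.40), hdrC (MJ0864; 1.70 ± 0.38), csm4 (1.68 ± 0.34) and rplV (1.59 ± 0.30). Others were rpsB (1.48, several spot sets), rplX (1.46), MJ0220 (1.44), MJ0217 (1.37), glnA (1.36 ± 0.33), ilvC (1.26), cfbA (1.22 ± 0.18), MJ0219 (1.19), minD (MJ0547; 1.10), cbiM (MJ1569; 1.10) and MJ0218 (1.07). After the loess 27 of the 44 named genes called at 7.8 atm were still called and 17 were not. Among the latter the sizes of MJ1155.1 (0.58), fwdA (0.56), MJ0217 (0.28), glnA (0.69) and csm3 (1.26) fell by more than 1.5 times in fold. The others that lost the call were MJ0219, rpl7ae, ileS, ilvC, purC, cbiM (MJ1569), MJECL28, MJ1513, MJ0449, MJ0933, MJ0572 and MJ0439. Outside the archaellum, genes that stayed called and fell by more than 1.5 times were fhcD (3.84-fold to 2.33-fold), hdrC (MJ0864; 3.26 to 2.06), csm4 (3.20 to 2.06) and rpsB (2.80 to 1.78). Called at smaller sizes before the loess were ilvN (0.83), rpl7ae (0.80), leuB (0.79), purC (0.78), ileS (0.74), csm2 (0.66, several spot sets) and csm5 (0.60, several spot sets). The A-type ATP synthase list had 6 of 9 genes called (9 when adjusted over the list alone), a median of 1.07 and an adjusted p of 3e-06 (adjusted p = 0.75 with an estimated correlation), and after the loess 2 genes called and a median of 0.51. Ribosomal protein genes had 4 of 15 called (10 when adjusted over the list alone), a median of 0.94 and an adjusted p of 3e-06 (adjusted p = 0.774 with an estimated correlation), and after the loess 3 called and a median of 0.61. Of the methanogenesis genes 2 of 29 were called, fhcD and fwdA (4 when adjusted over the list alone), with a list median of 1.26 and an adjusted p of 3e-06 (adjusted p = 0.806 with an estimated correlation). That list's call ended after the loess (0.278, median 0.23, 1 gene called) and without replicate 1 of this comparison (0.0804). The gene hmd had a log2 ratio of 2.20 ± 0.62 (adjusted p = 0.0568), mcrA (MJ0846) 1.19 ± 0.83 (0.364), frhA 1.62 ± 0.63 (0.138), sla 1.59 ± 0.85 (0.257) and psmA 1.10 ± 0.29 (0.0508), and none of these was called. The panel genes MJ1035 (1.61 ± 0.70, adjusted p = 0.176), thsB (1.26 ± 0.58, 0.196), mcrA (MJ0083; 0.85 ± 0.38, 0.185), rpoB (0.72 ± 0.34, 0.197) and MJ0285 (-0.26 ± 0.53, 0.774) were not called either. Of the 44 named genes called at 7.8 atm, 10 were called whichever array was left out, namely MJ0891 to MJ0897, MJ1155.1, rpsB and cfbA, and the calls of the other 34 ended without replicate 1 and also without replicate 2 of this comparison.

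Camera called 4 further lists at 7.8 atm. The methyl-coenzyme M reductase I and methyltransferase cluster had a median of 1.26 with 0 of 13 genes called (0 when adjusted over the list alone; adjusted p = 0.00593, and adjusted p = 0.806 with an estimated correlation). Its call ended after the loess (0.987, median 0.03) and without replicate 1 (0.626). Amino acid synthesis had 3 of 42 genes called, ilvC, ilvN and leuB (6 when adjusted over the list alone; median 0.23, adjusted p = 0.0128, and adjusted p = 0.806 with an estimated correlation), and was lost after the loess (0.118), without centring (0.226) and without replicate 2 (0.0804) or 3 (0.0654). Oxygen and oxidative stress proteins had 1 of 6 called, MJ0732 (1.14 ± 0.28), a homologue of flavoproteins that reduce oxygen (1 when adjusted over the list alone; median 1.01, adjusted p = 0.0386, and adjusted p = 0.806 with an estimated correlation), and were lost after the loess (0.278) and without replicate 1 (0.254). Genes of the extrachromosomal elements lay on the opposite side, with a median of -0.33 over 53 genes (adjusted p = 3e-06, and adjusted p = 0.622 with an estimated correlation). MJECL14 (-0.91 ± 0.17) and MJECL01 (-0.65 ± 0.16, several spot sets) were called on that side and MJECL28 (0.52 ± 0.13) on the archaellum side, and the counts were 12 and 1 when adjusted over the list alone. After the loess 6 were called on that side and 0 on the archaellum side. At 500 atm the extrachromosomal median was -0.14 (adjusted p = 0.0852), with 3 genes called on the other side (MJECL30, MJECL26 and MJECL12, the last printed as several spot sets) and 1 on the archaellum side (MJECL35; 0 and 0 when adjusted over the list alone). Other called genes away from the archaellum side at 7.8 atm were MJ1513 (-0.77 ± 0.18), MJ0401 (-0.73, several spot sets), MJ0011 (-0.69), MJ0449 (-0.68), MJ1303 (-0.61, several spot sets), MJ0933 (-0.54), MJ0572 (-0.53) and MJ0439 (-0.49).

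**Figure D2:**
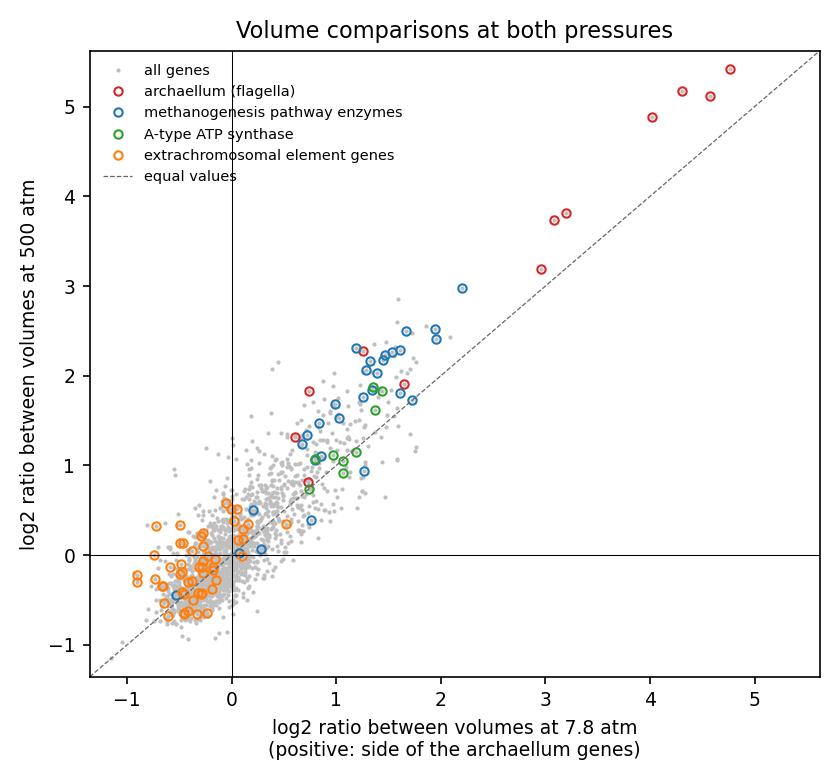
Log2 ratio between 600 and 200 ml at 500 atm (vertical) against 7.8 atm (horizontal), with 1 point per gene, 4 gene lists in colour and a dashed line at equal values. Of the archaellum genes, MJ0891 to MJ0897 lie beyond the named genes of the other lists at both pressures while flaJ, flaK and MJ0900 lie among them, and genes of the extrachromosomal elements lie mostly below 0 at 7.8 atm.

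Across genes the volume estimates at the 2 pressures correlated at r = 0.87. Of 241 and 83 genes called on the archaellum side 64 were shared, and on the other side 2 of 52 and 10. The 2 comparisons have no array and no condition in common, but both were estimated in one joint fit with a shared variance and dye coefficient. Genes are not independent of each other, so no test of the overlap is given. On all 6 volume arrays the 170 brightest genes were shifted to the archaellum side, by 0.29 to 1.62 on the log2 scale, which is a measured feature of the arrays that goes with the archaellum, methanogenesis, ATP synthase and ribosomal genes. Among random lists of the same size and brightness, the methanogenesis median at 500 atm stood at percentile 100 and the archaellum median at percentile 100, the ATP synthase median at 70.3 and the ribosomal median at 87.3. At 7.8 atm the percentiles were 99.7 for methanogenesis, 100 for the archaellum, 97.6 for the ATP synthase and 98.8 for ribosomal proteins. The random lists drew genes singly, so they can spread less than lists of genes that vary together. Each draw came from the 50 genes nearest in brightness, so for the brightest members it can lean to dimmer genes, which raises the percentile.

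**Figure D3:**
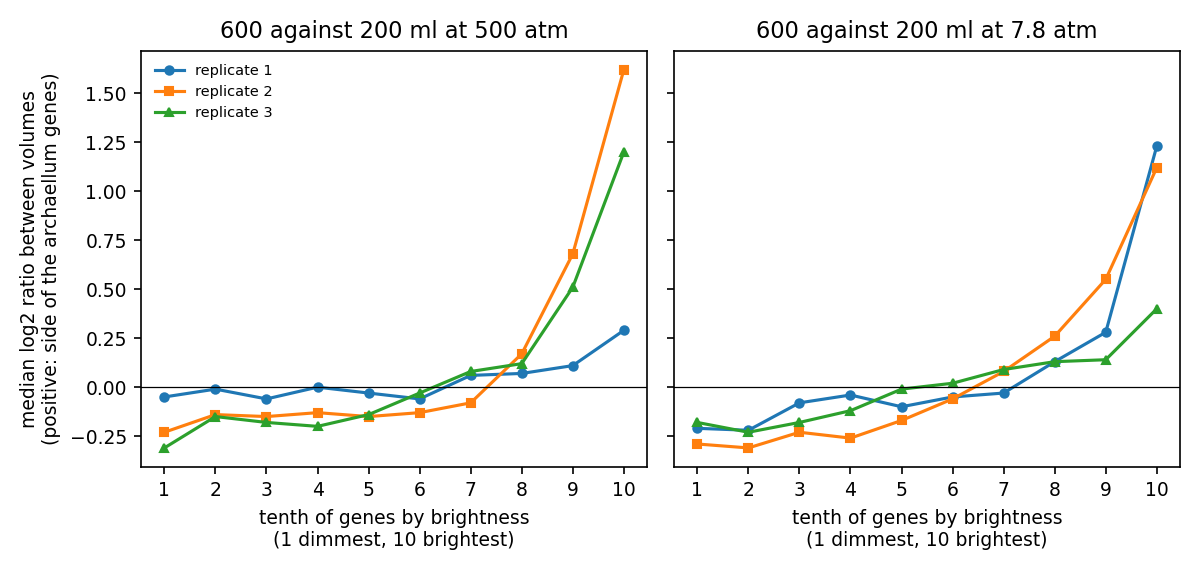
Median log2 ratio between 600 and 200 ml in 10 groups of genes of rising brightness, with 1 line per array at 500 atm (left) and 7.8 atm (right). The brightest group lay on the archaellum side on all 6 arrays, by 0.29 at the least and 1.62 at the most.

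Few transcripts were called for pressure, and all of those calls were in 200 ml. In 200 ml, MJ0334 differed 6.04-fold between 500 and 7.8 atm (log2 2.60 ± 0.34, n = 4 arrays, adjusted p = 0.00645), with single arrays from 1.11 to 3.27. On the same side lay MJ0363 (1.52 ± 0.21, 2.87-fold), MJ0352 (1.39 ± 0.24, 2.62-fold), MJ0289 (1.28 ± 0.22, 2.42-fold) and MJ0745 (0.90 ± 0.16, 1.86-fold). On the other side lay MJ1515 (-1.22 ± 0.16, 2.32-fold, adjusted p = 0.00645) and cas7a, a subunit of the CRISPR interference complex (-0.98 ± 0.16, 1.97-fold, adjusted p = 0.0195). MJ0334, MJ0352 and MJ0363 stand near each other in the genome, in a run of 33 genes from MJ0334 to MJ0366 whose median was 0.66.

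These 7 genes were all that limma called in 200 ml, 5 on the MJ0334 side and 2 on the other, with 255 genes at an unadjusted p under 0.05, and each had the same sign on all 4 arrays. The count was 165 (4 to 161) without centring, 152 (78 to 74) with arrays scaled to one spread, 0 without replicate 1, 2 or 3 of this comparison and 20 without replicate 4. It was 42 with the replicate number as a block, 465 with array weights and 33 in the closed-loop fit. Without replicate 2, the array with the conflicting volume label, the smallest adjusted p of the 7 genes was 0.0894. Replicates 1 and 3, whose labels do not conflict, ended the calls in the same way. Single genes were past the threshold in 24 of 28 alternatives and left-out arrays for MJ0334, with log2 sizes of 2.11 to 3.26, and in 17 of 29 for MJ0745.

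**Figure D4:**
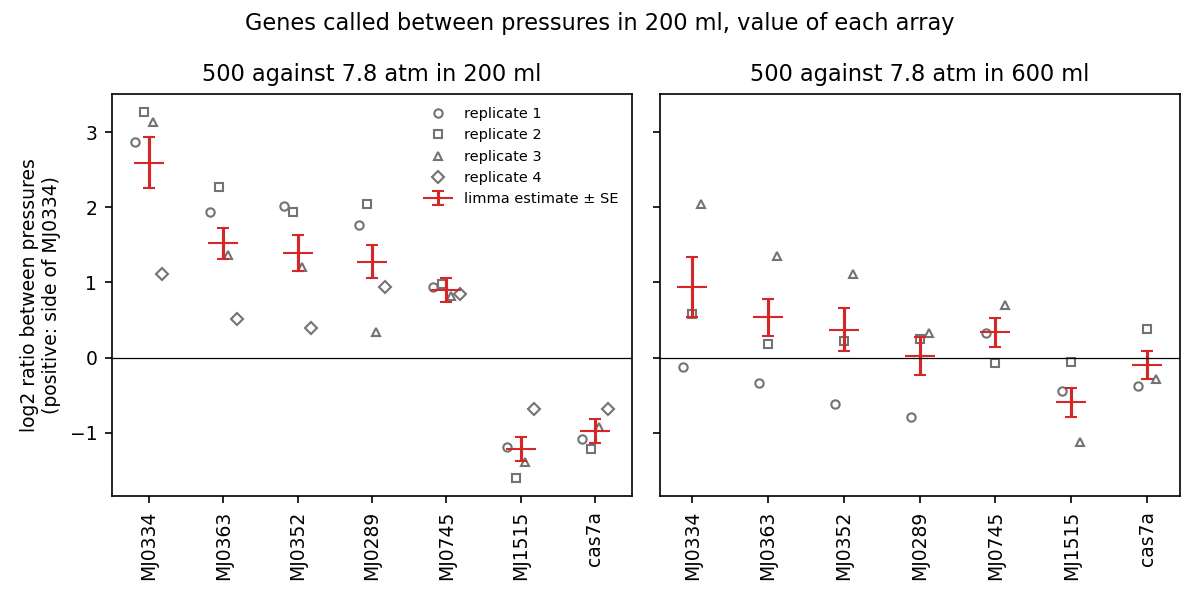
Log2 ratio between 500 and 7.8 atm of the 7 genes called in 200 ml, in 200 ml (left) and in 600 ml (right), where grey symbols are single arrays, red bars are limma estimates with their SE, and positive values lie on the side of MJ0334. In 200 ml each gene kept its sign on all 4 arrays, and in 600 ml MJ0334 ranged from -0.12 to 2.04.

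In 600 ml no gene was called by limma between 500 and 7.8 atm, with 150 genes at an unadjusted p under 0.05. MJ0334 had a log2 ratio of 0.94 ± 0.40 (adjusted p = 0.519), MJ1515 of -0.60 ± 0.19 (0.517), and cas7a of -0.10 ± 0.18 (0.833). The others of the 7 genes were MJ0363 (0.54), MJ0352 (0.37), MJ0289 (0.02) and MJ0745 (0.34). The difference between the volumes was tested by the interaction, which called none of them (adjusted p = 0.366 for MJ0334). Across genes the pressure estimates in 200 and 600 ml correlated at 0.55. None of the 12 panel genes was called in either volume. Their log2 ratios ran from -0.59 (thsB, the thermosome chaperonin) to 0.58 (hmd) in 200 ml, with a smallest adjusted p of 0.36. In 600 ml they ran from -0.74 (rpoB) to 0.31 (frhA), with a smallest adjusted p of 0.52. The small heat shock protein gene MJ0285 was at -0.29 in 200 ml and -0.26 in 600 ml.

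Small shifts of whole lists were called by camera in the pressure comparisons. In 200 ml the 16 aminoacyl-tRNA synthetase genes had a median of -0.25 (0 genes called, 0 when adjusted over the list alone; adjusted p = 0.00154, and adjusted p = 0.75 with an estimated correlation). In 600 ml the same list stood at -0.20 (0 called, 1 when adjusted over the list alone; adjusted p = 0.00808, and adjusted p = 0.754 with an estimated correlation), a call lost without replicate 1 (0.163). Amino acid synthesis had a median of -0.26 over 42 genes in 600 ml (0 called, 0 when adjusted over the list alone; adjusted p = 0.000154, and adjusted p = 0.75 with an estimated correlation). Ribosomal proteins lay at -0.39 (0 and 0; adjusted p = 0.0456, and adjusted p = 0.842 with an estimated correlation). That call was lost without replicate 2 (0.69) or 3 (0.0918) of the comparison, without replicate 2 (0.0502) or 4 (0.0539) of the pressure comparison in 200 ml, and without replicate 1 of volume at 7.8 atm (0.107), and also without the genes of several spot sets (0.114). On the MJ0334 side in 600 ml lay hydrogenases and heterodisulfide reductase, at 0.31 over 31 genes (0 and 0; adjusted p = 0.00309, and adjusted p = 0.75 with an estimated correlation), lost without replicate 1 (0.0616) or 3 (0.568). Oxygen and oxidative stress proteins also lay there, at 0.56 over 6 genes (0 and 0; adjusted p = 0.0298, and adjusted p = 0.806 with an estimated correlation), lost without replicate 1 (0.533) or 3 (0.334) and without replicate 1 of volume at 7.8 atm (0.0548).

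Whether the pressure difference changed with volume, or the volume difference with pressure, was tested as an interaction over all 13 arrays. Limma called no gene, with 155 at an unadjusted p under 0.05. The 7 archaellum genes from MJ0891 to MJ0897 were among the largest in both volume comparisons, and as a list the archaellum had a positive interaction (median 0.52, adjusted p = 5.36e-05, and adjusted p = 0.75 with an estimated correlation), a larger volume difference at 500 than at 7.8 atm. After the loess the median was 0.29 (adjusted p = 0.0407), and MJ0891 was at 3.67 at 500 atm and 3.82 at 7.8 atm. No archaellum gene was called singly (5 when adjusted over the list alone). Nitrogen assimilation genes had a median of 0.57 over 7 genes (0 called, 4 when adjusted over the list alone; adjusted p = 0.00154, and adjusted p = 0.349 with an estimated correlation). At 500 atm the volume difference of this list was led by glnA and by the regulatory genes glnK1 (MJ1344; 1.23 ± 0.38) and glnK1 (MJ0059; 1.12 ± 0.33), which were at 0.01 and -0.13 at 7.8 atm. Single arrays at 500 atm ran from -0.06 to 2.33 for glnK1 (MJ1344) and from -0.07 to 2.19 for glnK1 (MJ0059).

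A smaller interaction median was called for amino acid synthesis (0.19, 0 called and 0 when adjusted over the list alone; adjusted p = 0.0109, and adjusted p = 0.806 with an estimated correlation). So were those of the extrachromosomal elements (0.14, 0 and 0; adjusted p = 0.0208, and adjusted p = 0.774 with an estimated correlation) and CRISPR-associated proteins (-0.10, 0 and 0; adjusted p = 0.00889, and adjusted p = 0.622 with an estimated correlation). The call of amino acid synthesis was lost without replicate 4 of pressure in 200 ml (0.0551), replicate 2 of pressure in 600 ml (0.0547) or replicate 1 of volume at 7.8 atm (0.134). That of the extrachromosomal elements was lost without replicate 2 of pressure in 200 ml (0.0987), replicate 1 of pressure in 600 ml (0.203), replicate 3 of volume at 500 atm (0.0512) or replicate 2 of volume at 7.8 atm (0.0566), after the loess (0.105) and without centring (0.118). The pressure arrays and the volume arrays each give an estimate of this interaction, and across genes the estimates correlated at 0.49 with a slope of 0.59. They are not independent as far as the values show, since arrays of the same number in pressure in 600 ml and volume at 500 atm deviated alike (r = 0.72, 0.87 and 0.43). The correlation was 0.132 without replicate 2 of pressure in 600 ml, 0.213 and 0.323 without replicates 4 and 3 of pressure in 200 ml, 0.236 without replicate 2 of volume at 500 atm and 0.327 without replicate 1 of volume at 7.8 atm. With the replicate number as a block, limma called 2 genes for the interaction.

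Of the 120 pairs of list and result, camera called 25 with the preset correlation and 0 with an estimated one, where the smallest adjusted p was 0.349. Fry called 10 pairs, 6 of them also called by camera, among them the archaellum in both volume comparisons (adjusted p = 1.85e-05 and 4.42e-05). Lists that camera did not call in any result were formate dehydrogenase (medians -0.26 and -0.38 for volume at 500 and 7.8 atm), RNA polymerase and general transcription factors (0.25 and 0.03), translation factors (0.91 and 0.44), chaperones and proteasome (0.97 and 0.39), and acetyl-CoA and pyruvate synthesis (0.35 and 0.37). So were methanogenic cofactor synthesis (0.03 and 0.01), cobalamin and tetrapyrrole synthesis (-0.07 and -0.14), purine and pyrimidine synthesis (0.26 and 0.16), DNA replication with repair and histones (0.28 and 0.06), metal transport (0.15 and 0.08), phosphate transport (0.03 and -0.08) and cell division (0.85 and 0.51). Of these, fry called purine and pyrimidine synthesis and cell division for volume at 500 atm (adjusted p = 0.0167 for each). Without centring camera called translation factors (0.0392) and chaperones and proteasome (0.0496) at 500 atm. It called purine and pyrimidine synthesis for the interaction after the loess (0.0405). Camera also called purine and pyrimidine synthesis for volume at 500 atm without the genes of several spot sets (0.0402). When adjusted over the list alone, these lists had the following numbers of genes past the threshold for volume at 500 and 7.8 atm. Purine and pyrimidine synthesis had 9 and 0, chaperones and proteasome 6 and 1, acetyl-CoA and pyruvate synthesis 4 and 0, metal transport 4 and 1 and cell division 3 and 3. Translation factors had 2 and 0, cofactor synthesis 2 and 0, cobalamin and tetrapyrrole synthesis 1 and 1, formate dehydrogenase 0 and 1, and the others 0 and 0. Among lists called in other results, aminoacyl-tRNA synthetases stood at 0.26 and 0.17 for volume (adjusted p = 0.067 and 0.13), oxygen and oxidative stress proteins at 0.96 at 500 atm (0.0731), hydrogenases at 0.08 at 7.8 atm (0.351), and nitrogen assimilation at 0.62 and -0.13 (0.12 and 0.859). Of these, fry called nitrogen assimilation at 500 atm (adjusted p = 0.0219). Camera called oxidative stress proteins at 500 atm without centring (0.0219) and aminoacyl-tRNA synthetases there after the loess (0.0226). For pressure, fry called CRISPR-associated proteins in 200 ml (0.0321), and camera called ribosomal proteins in 200 ml without centring (0.0112) and the ATP synthase in 600 ml after the loess (0.0495). For the interaction, camera called 4 further lists without centring, hydrogenases (0.0437, and 0.0132 after the loess), methanogenesis (0.0124), the methyl-coenzyme M reductase I cluster (0.00208) and oxidative stress proteins (0.0179). The 21 CRISPR-associated genes had medians of -0.23 and -0.09 but means of 0.14 and 0.13 (0.819 and 0.857), with 6 and 4 genes called on the archaellum side and 1 and 0 on the other. In the pressure comparisons the medians of uncalled lists ran from -0.18 to 0.20 in 200 ml and from -0.31 to 0.07 in 600 ml. Of the lists too small to test, isoprenoid lipid synthesis had medians of 0.16 and 0.19 for volume at 500 and 7.8 atm, the methyl-coenzyme M reductase II cluster 0.94 and 0.85, and protein export 0 and -0.13, with 0 genes called by limma in any.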

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

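The tests of the drift of bright genes against the dyes, of RNA amount or saturation, of the archaellum after a loess, and of the stretch of neighbouring genes after a loess were chosen after the result was seen, and the tests of methanogenesis against brightness, of spot sets and of other groupings of the arrays were not.

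A difference of the volume effect between pressures was called for 5 gene lists by camera at its preset correlation, in the interaction over 13 arrays, and for none of them with an estimated correlation (adjusted p 0.349 to 0.806). Fry called 1 of the 5, nitrogen assimilation (adjusted p = 0.0278). All these tests took the arrays as independent, and their p-values may be too small because arrays of the same number in 2 comparisons deviated alike. The calls of amino acid synthesis and of the extrachromosomal elements each ended without any 1 of several arrays (adjusted p up to 0.134 without replicate 1 of volume at 7.8 atm and up to 0.203 without replicate 1 of pressure in 600 ml). The interaction medians on the log2 scale were 0.52 for the archaellum, 0.57 for nitrogen assimilation, 0.19 for amino acid synthesis, 0.14 for the extrachromosomal elements and -0.10 for CRISPR-associated proteins. Limma called no single gene (155 at an unadjusted p under 0.05). For the archaellum the volume differences lay on the same side at both pressures, and the interaction has the sign of a larger one at 500 atm. After a loess on brightness the difference of the list medians nearly vanished (2.17 at 500 atm and 2.14 at 7.8 atm), the interaction median was 0.29 (adjusted p = 0.0407), and for MJ0891 the difference turned (3.67 at 500 atm and 3.82 at 7.8 atm). Other groupings of the arrays say nothing about chance here, since the real value is 0 and all 100 random groupings had to reach it. The highest of the others called 507 genes, and why it did was not tested.

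Spots outside the gene tests passed the threshold in 1 comparison. Of 1337 spots with no gene in the annotation, 823 passed an adjusted p of 0.05 in limma for pressure in 200 ml, all on the side of MJ0334, with a largest log2 size of 1.67. In the other comparisons and the interaction 0 passed, with 34 at an unadjusted p under 0.05 for pressure in 600 ml, 187 and 35 for volume at 500 and 7.8 atm and 29 for the interaction. These spots were dim, with array medians of 7.42 to 9.62 in log2 brightness against 9.58 to 12 for spots with a gene. Their median log2 ratios relative to the median gene were 1.07, 1.89, 0.88 and 0.15 on the 4 arrays. Single arrays of the other comparisons also had shifts, with -1.13, 0.58 and -0.24 for pressure in 600 ml, -0.08, -0.57 and -1.28 for volume at 500 atm and -0.18, 0.16 and 0.09 at 7.8 atm. What they hold is not given in the sources used here, and no cause was tested.

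Bright genes lay on the archaellum side of the volume comparisons, and technical explanations for this were weighed. A dye bias that grows with brightness would turn with the dye swap, but the brightest genes lay on the same side on 6 of 6 volume arrays of both dye orientations, which argues against it. A ratio that drifts with brightness as the whole cause is argued against for the archaellum, where 11 of 12 genes were still called at 500 atm after a loess on brightness. For methanogenesis at 500 atm the median of 1.77 stood at percentile 100 of random lists of the same size and brightness (95th percentile 1.47). After the loess camera still called that list (median 0.58, adjusted p = 0.00931). The random lists drew genes singly, while 13 of the list's genes form 1 cluster. With an estimated correlation camera did not call the list before the loess (adjusted p = 0.806). Drift as the whole cause is therefore argued against there only as far as the genes vary independently. At 7.8 atm the methanogenesis median of 1.26 stood at percentile 99.7, but after the loess it was 0.23 and the call ended (adjusted p = 0.278), so the drift is not excluded there. At 500 atm the ATP synthase median of 1.11 and the ribosomal median of 1.03 stood at percentiles 70.3 and 87.3, within the range of the random lists. After the loess camera still called both lists there (medians 0.76 and 0.64, adjusted p = 0.00185 and 0.00449). The 2 checks differ, so drift as the whole cause is neither excluded nor shown for these lists. At 7.8 atm they stood at percentiles 97.6 and 98.8. An amount of RNA or a saturation that differed between the volumes cannot be told apart from a change in the cells, because it goes with the condition, and the median shift of the brightest genes was 1.16. Part or all of the size of the methanogenesis, ATP synthase and ribosomal differences may therefore come from it.

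A stretch of neighbouring genes from MJ0334 to MJ0366 lay on one side for pressure in 200 ml. Its 33 genes had a median of 0.66, with 27 above 0. It was picked out for that median, and neighbouring genes correlated at 0.35 throughout the chromosome, so no test of it against chance is given. Of the 33 genes 14 were among the dimmest 25%. A drift with brightness as the whole cause is argued against, since after a loess on brightness the 33 genes still had a median of 0.56 (lower quartile 0.03), and one of 0.52 without replicate 1, for which the brightness of replicate 2 had been used. On single arrays the median was 0.73, 0.80, 0.56 and 0.13 in 200 ml and -0.04, 0.40 and 0.40 in 600 ml. The dim spots with no gene, on which the loess was not fitted, ranked the arrays in 200 ml alike (1.07, 1.89, 0.88 and 0.15). In 600 ml those spots stood at -1.13, 0.58 and -0.24, and whether their shift and that of the stretch are related was not tested. Whether a shared regulation or a difference in the DNA of the cultures lies behind the stretch was not tested either.

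Spot sets of the same gene disagreed, at an r under 0.5 across arrays, for 105 of 166 genes printed as several sets. Weak or failed spots in 1 of the sets are a candidate explanation, since the median gap in log2 brightness between sets was 1.15 for those genes and 0.73 for the 61 whose sets agreed (1-sided permutation test, p = 0.011). No biological explanation was tested.

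The counts of called genes were compared with those from other sign assignments of the arrays within each comparison, which are too few for a share under 0.05. Of 8 assignments in the pressure comparison in 200 ml, 1 gave as many genes as the real value of 7, and the highest other gave 0. In 600 ml all 4 of 4 gave 0. For volume, 1 of 4 gave as many as the real values of 293 at 500 atm and 93 at 7.8 atm, and the highest other gave 0 at both.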

How the results depend on the processing

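The loess on brightness and the fits without genes of several spot sets, without the dimmest 25% of genes and without 2 poorly agreeing arrays were chosen after the results were seen, and the other alternatives before the data were examined. The cause of each change below was not tested unless one is given.

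For the named genes, 1734 of 2255 alternative values had the same side and call as reported, 457 lost the call, 46 gained one and 18 changed side. With 1 array left out, 1367 of 1885 were the same, 498 lost the call, 16 gained one and 4 changed side. Where an array was left out the fit had fewer samples.

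For pressure in 200 ml the 7 called genes became 165 without centring, 152 with arrays scaled to one median absolute deviation, 3 without the noisiest 25% of genes, 42 with the replicate number as a block, 465 with array weights (whose estimation gave a convergence warning), 0 with the conflicting label left out, 55 and 534 from the arrays of the comparison only without and with a dye coefficient, and 33 in the closed-loop fit. Leaving out the noisiest genes takes genes out of the test, and the 3 genes were all among the 7. The range over single arrays left out was 0 to 20. In 600 ml the count of 0 became 1 without centring and 1 in the closed-loop fit, and was 0 without any single array (limma, 150 genes at an unadjusted p under 0.05 as reported).

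For volume at 500 atm the 293 genes became 135 with a 2-fold minimum, 107 with scaled arrays, 180 with the block, 14 and 137 from the arrays of the comparison only without and with a dye coefficient, and 597 in the closed-loop fit. The count was 273 without centring and 236 after the loess, of which 133 and 174 genes were shared with the 293. The range over arrays left out was 19 to 442. At 7.8 atm the 93 genes became 51 with a 2-fold minimum, 51 without the noisiest genes, 57 with the block, 337 with array weights, 57 with the conflicting label left out, 163 and 207 from the arrays of the comparison only without and with a dye coefficient, 304 in the closed-loop fit and 36 without the 2 poorly agreeing arrays, 17 of them shared. It was 64 without centring and 74 after the loess, with 28 and 55 shared. The 51 genes called without the noisiest genes, a fit that takes genes out of the test, were all among the 93. The range over arrays left out was 13 to 149.

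The interaction count of 0 became 1 without centring and 2 with the block, and stayed 0 without any single array. The correlation of the loop across genes was 0.493 and ranged from 0.132 to 0.603. The 25 called pairs of list and result became 0 with an estimated correlation and 10 with fry, and ranged from 20 to 34 over arrays left out.

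Values that changed side at 500 atm were, after the loess, frhA (-0.11), thsB (-1.13) and hdrC (MJ0864; -0.044). MJ0285, at 0.01 as reported, was at -0.009 without the dye coefficient, -0.37 without centring, -0.41 with scaled arrays, -0.094 with the block, -0.16 with array weights, -0.009 from the arrays of the comparison only without a dye coefficient, -0.067 in the closed-loop fit and -0.67 after the loess. Without replicate 2 of this comparison thsB was at -0.40 (range over arrays left out -0.40 to 1.64) and MJ0285 at -0.99 (range -0.99 to 0.62), and without replicate 2 of pressure in 600 ml MJ0285 was at -0.03. At 7.8 atm, after the loess, mcrA (MJ0846) was at -0.41, mcrA (MJ0083) at -0.35, thsB at -0.079, rpoB at -0.041 and sla at -0.18. Without the 2 poorly agreeing arrays mcrA (MJ0846) was at -0.15 and sla at -0.039, and without replicate 3 of this comparison MJ0285 was at 0.13 (range -0.846 to 0.13). The alternatives on missing values and on a filter of genes were not run, as no value was missing. The number of arrays limits the precision of all values.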

Other observations

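The tests of the direction of the archaellum difference and of array numbers across comparisons were chosen after the results were seen, and so was the gene nifH, which lies outside the rule for named genes.

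All 12 archaellum genes were called on 1 side for volume at 500 atm. One hypothesis is that they are higher in 600 ml, where gas transfer limits growth, since low hydrogen may raise archaellum synthesis in this organism. The deposited ratios cannot decide it, because the labels do not state which channel is the numerator, and either direction gives the same 12 genes.

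Arrays with the same replicate number in the pressure comparison in 600 ml and the volume comparison at 500 atm deviated from their comparison means alike, at r = 0.72, 0.87 and 0.43 across genes. The mean of 0.67 was above that of the other 5 pairings of the arrays (highest 0.34), and after the loess the values were 0.53 and 0.31. Genes are not independent replicates. Both comparisons hold the condition of 500 atm and 600 ml. Replicates 2 deviated alike in every pair of comparisons (r = 0.30 to 0.87), also between the pressure comparisons (0.50) and between the volume comparisons (0.44), which share no condition. For replicates 1 and 3 the other pairs of comparisons gave -0.48 to 0.37. The labels do not say whether arrays of the same number shared a culture or a labelling, and with 6 pairings no share under 0.05 can be reached.

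Behind the interaction of nitrogen assimilation stood glnK1 (MJ1344) at 1.13, glnK1 (MJ0059) at 0.98, glnA at 0.82 and nifH at 0.57, none called singly over all genes.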
